A study of Homo sapiens with 3 samples.

How the data were processed

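CUT&Tag libraries were made from HSC3 cells with PD-L1 knocked out and a Flag-tagged PD-L1 overexpressed, per the labels. The antibody was left on for 2 h. The 3 libraries were an untagged control with IgG, tagged cells with IgG, and tagged cells with anti-Flag, with 1 library per group. Per the submitters' processing notes, fastp, BWA and MACS3 were used on GRCh38, with no versions given in the sources used here. The deposited peak list has no header. It was assigned to the anti-Flag library because its peak names fit that library's description and no other's. Whether a control library entered the peak calling, and which, is not given in the sources used here.

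For each peak, the authors deposited a score, a fold enrichment at the summit, a −log10 p, a −log10 q and the offset of the summit. The deposited score equals 10 times the −log10 q, rounded down, in 100% of peaks, and was not used. The lowest deposited −log10 q was 1.31. No fold or score was rescaled.

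Fragment numbers behind each summit were recovered from the deposited fold and −log10 p. The formula was chosen after the values were seen: fold is the scaled number of fragments plus 1, over the background plus 1, and p is the Poisson tail above the scaled number rounded down. A scale of 0.850 and a floor background of 0.523 fragments gave the −log10 p within 0.001 for 56863 of 56865 peaks, and within 0.00221 for the other 2, the mitochondrial peak and the peak in TET3. Fragment numbers of that pair are less certain. For 9 peaks a second whole number also came within 0.001. In 48.6% of peaks the background was at the floor. Of 29202 backgrounds above the floor and below 20, 7519 (25.7%) lay within 0.0005 of a whole number of unscaled fragments, and 0 lay that close to a whole number of scaled anti-Flag fragments. The background was therefore read as a library other than the scaled anti-Flag one, a check chosen after seeing the data. Tested on simulated data with 5000 peaks, the recovery returned 100% of fragment numbers at a scale of 0.83, but 75.4% at a scale of 0.8, where scaled numbers are often whole and rounding down is a tie. The largest error there was 10 fragments. The sequencing depth of each library was not analysed here. The recovered fragments give the precision of single peaks, and intervals cover counting error only, not the selection of summits by peak calling.

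Genes came from an NCBI RefSeq gene table of GRCh38.p14 with 20033 protein-coding genes on chromosomes 1 to 22, X and Y. The table gives start and end of each gene, with no strand, exons or sequence. The design fixed before the data were examined used summits within 1 kb of a transcription start site. This was replaced by summits within 1 kb of either annotated gene end, and the exon split at CD274, the tests of 16 motifs, and placement matched on base composition were not run. Chromosome stretches were cut where neighbouring genes and peaks lay over 1 Mb apart, and each of 100 random placements drew positions within those stretches on the same chromosome.

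The 16 gene lists hold 34 to 78 genes each and 736 distinct genes. All were matched to the gene table, 1 by an older symbol. Lists were tested by two-sided Fisher's exact tests against all other protein-coding genes with Benjamini-Hochberg adjustment at 0.05. Genes are not replicates, so these tests describe this peak list. The list test was tested on simulated data with lists of 40 genes. Random placement gives fewer genes with a summit than observed, so the simulation raised the background by a probability set by hand, to a mean share of 12.7% in lists with nothing planted.

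Genes are named by a rule fixed beforehand: CD274, SOD2, GPX4, SLC7A11, AIFM2, DHODH and NFE2L2; the 4 members with the highest fold at a gene end in the ferroptosis suppressor, ferroptosis driver and antioxidant lists and the 2 highest in every other list; the 10 highest of all genes; and the 5 highest peaks. Ties were broken by symbol. One gene that the rule picks is not reported here. Alternatives fixed beforehand were a −log10 q of at least 5, a fold of at least 5, distinct intervals, main chromosomes only, a 3 kb window, and any overlap with the 1 kb window. Chosen after seeing the data were the copies shifted by 5 to 50 kb, a −log10 q of at least 10, the ends beside divergent transcripts at 1 kb and 500 bp (partner within 5 kb, gene longer than 5 kb), gene spans against the local density and against 10000 random lists matched on gene length in 20 classes, the split by fragments, the profile around gene ends, and the density of stretches. Shares have Wilson and counts exact Poisson 95% intervals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.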

Results

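The series asked where tagged PD-L1 sits on chromatin. PD-L1 is the immune checkpoint ligand encoded by CD274, and the series title links it to sensitivity to ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation. The cells were HSC3, a human tongue squamous carcinoma line, in which PD-L1 had been knocked out and a Flag-tagged PD-L1 overexpressed. The assay was CUT&Tag, in which an antibody directs the Tn5 transposase to cut and tag nearby DNA. There were 3 libraries with 1 library per group: cells without the tag with control IgG, tagged cells with control IgG, and tagged cells with anti-Flag. The peak list of the anti-Flag library was analysed. With no replicate, no test between samples was possible, and values of the control libraries by themselves were not analysed here.

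The anti-Flag library had 56865 peaks, and most were shallow. Their median width was 475 bp and the authors' fold enrichment at the summit had a median of 4.56, with quartiles of 3.86 and 5.68. The highest fold on chromosomes 1 to 22, X and Y was 15.88, inside ADAMTS13, which encodes the protease that cleaves von Willebrand factor. A median summit rested on 8 recovered fragments, for which the exact Poisson 95% interval is 3.45 to 15.8. At the genome-wide floor of the background, that interval spans folds of 2.58 to 9.46. At most 8 fragments lay under 52.4% of summits, and 934 peaks (1.64%) had 20 or more. These intervals cover counting error only. Summits were kept only where a peak was called, with 5 fragments at the lowest, and the intervals do not allow for that selection. The authors' fold and −log10 q were used only within this list, to describe, rank and filter peaks and to recover fragments from fold and p.

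The 5 peaks with the highest fold lay on GRCh38 as follows. The peak inside ADAMTS13 (chromosome 9, 133442354 to 133443376) had a fold of 15.88 from 30 fragments (95% interval 20.2 to 42.8). The next (chromosome 8, 138497856 to 138498553), at a fold of 15.4 from 29 fragments, had its summit 487 bp outside FAM135B. A peak on chromosome 21 (9343081 to 9344258) overlapped the lncRNA gene LOC101930100 and had a fold of 15.2 from 26 fragments. Its nearest protein-coding gene, LOC101927345, was 15969 bp from the summit. A peak on chromosome 11 (70233750 to 70234479) also had a fold of 15.2, and its summit lay 26579 bp from FADD, an adaptor of death receptors. The peak inside DHRS2, a short-chain dehydrogenase gene (chromosome 14, 23639079 to 23639771), had a fold of 14.6 from 25 fragments. The intervals of these peaks overlap, so their order was not resolved at this depth. Whether they lie in exons or introns was not analysed here.

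At CD274 itself, the gene that was knocked out and reintroduced as a tagged copy, no peak was listed. Its span (chromosome 9, 5450542 to 5470554) and the 5 kb on either side held 0 summits, where the density of the surrounding 2 Mb gives 0.426. A gene of this length has 0 summits by chance 65.3% of the time at that density. The nearest summit lay 47628 bp from the gene, with a fold of 4.56 from 7 fragments (95% interval 2.81 to 14.4). Which part of the gene the knockout removed was not given in the sources used here.

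Of the core ferroptosis and oxidative stress genes fixed beforehand, SOD2, AIFM2 and DHODH had 1 summit each within their spans, and GPX4, SLC7A11 and NFE2L2 had 0. SOD2, the mitochondrial superoxide dismutase (chromosome 6, 159669069 to 159762281), had a summit at 159693725 with a fold of 4.02 from 13 fragments (95% interval 6.92 to 22.2). That summit lay 24656 bp from the nearer annotated end, and its distance to the start sites of shorter transcripts was not analysed here. SOD2 therefore counts as without a gene-end summit in the antioxidant list below, wherever those start sites lie. AIFM2, the ubiquinone oxidoreductase that suppresses ferroptosis (chromosome 10, 70112271 to 70132825), had a summit at 70127207, 5618 bp from an end, with a fold of 3.86 from 17 fragments. DHODH, the pyrimidine synthesis enzyme of the inner mitochondrial membrane (chromosome 16, 72008744 to 72027659), had a summit at 72016505 with a fold of 3.72 from 7 fragments. The nearest summit lay 34918 bp from GPX4, the lipid hydroperoxide reductase, 138462 bp from SLC7A11, the cystine transporter, and 10054 bp from NFE2L2, the regulator of antioxidant genes. The local density gives 1.74 summits for SOD2, 0.760 for AIFM2 and 0.576 for DHODH, over each annotated span with 5 kb on either side. As a number over that whole length, 1 summit in each was not distinguishable from the surrounding density. This count does not weigh where a summit lies, so a summit at a start site inside the SOD2 span is not excluded. The local density gives 0.150 for GPX4, 0.714 for SLC7A11 and 0.958 for NFE2L2, at which 0 summits arise by chance 86.1%, 49.0% and 38.4% of the time. For GPX4, the 2 Mb on its left run past the start of the chromosome but were counted in full. Its 0.150 is therefore too low and its 86.1% too high.

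Peak summits gathered at the ends of protein-coding genes. Of 56715 summits on chromosomes 1 to 22, X and Y, 2432 (4.29%, Wilson 95% interval 4.12 to 4.46) lay within 1 kb of an annotated gene end. Random placement on the same chromosomes gave a mean of 1431 with a range of 1349 to 1526 over 100 placements, so the observed number was 1.70 times the random mean. Summits in protein-coding gene spans made up 50.6% of the list against 44.3% with random placement and 47.7% in copies of the summits shifted by 5 to 50 kb, and summits in lncRNA gene spans 16.11% against 16.04%. Pseudogene spans held 2.70% of summits against 1.79%. Within genes longer than 20 kb, the 500 bp just inside the end held 21.3 summits per 1000 ends and the 500 bp just outside 16.6. At 9500 to 10000 bp from the end, the bins held 9.99 inside and 8.26 outside, so the level differed between the sides there too. Inside the gene, the bin at 2500 to 3000 bp still held 14.0.

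**Figure D1:**
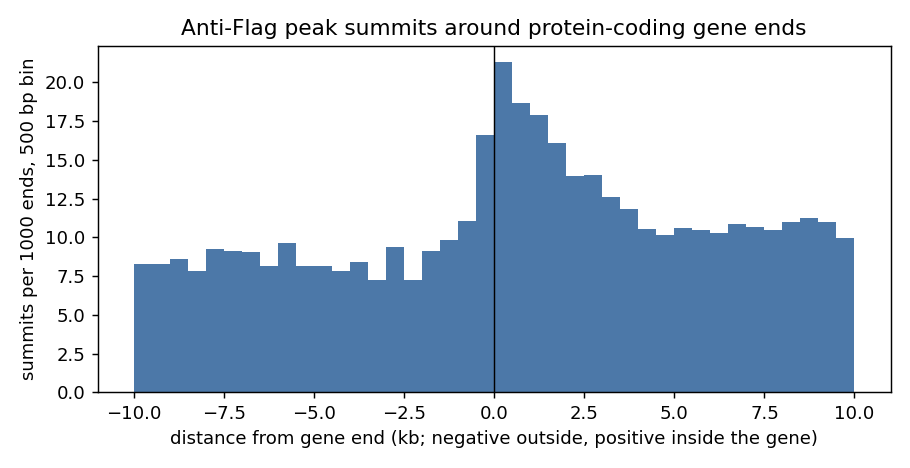
Summits per 1000 gene ends (vertical axis) in 500 bp bins by distance in kb from either annotated end of protein-coding genes longer than 20 kb (horizontal axis, negative outside and positive inside the gene). The bin just inside the end holds 21.3 and the bin just outside 16.6.

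Summits with more fragments lay at gene ends more often. The share within 1 kb was 2.28% (Wilson 95% interval 2.05 to 2.54) for summits of 5 to 6 fragments and 13.4% (11.3 to 15.8) for those of 20 or more. Copies of the same summits shifted by 5 to 50 kb gave 1.90% and 5.76%, so the ratio to the shifted copies went from 1.20 to 2.33. The annotation used here gives no strand, so start and end of a gene could not be told apart for most genes. Genes with an annotated divergent transcript are a selected group, so their result may not hold for other genes. For 526 genes with an annotated divergent transcript, which marks the start, 47 (8.94%) had a summit within 1 kb of the start and 28 (5.32%) within 1 kb of the far end. Of these, 45 genes had a summit at the start only and 26 at the far end only, and the exact two-sided McNemar test gave p = 0.0319. This test was chosen after seeing the data, and with a 500 bp window, also tried, 28 starts and 16 far ends had a summit, with an exact p = 0.0961. The shifted copies gave means of 18.8 at starts and 26.2 at far ends, with ranges of 13 to 25 and 17 to 38. Observed numbers were thus 2.51 times the shifted mean at starts and 1.07 times at far ends. In these genes the number at far ends lay within the range of the shifted copies.

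**Figure D2:**
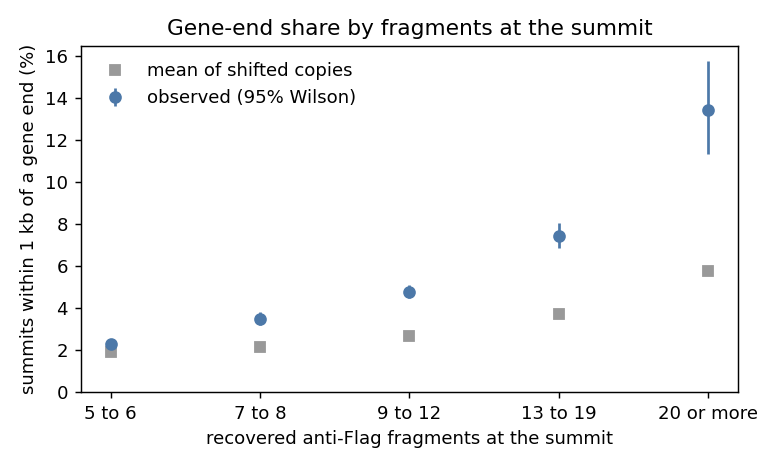
Share of summits within 1 kb of a protein-coding gene end (vertical axis, percent) by the number of recovered anti-Flag fragments at the summit (horizontal axis). Circles are observed shares with Wilson 95% intervals and squares the mean of 8 shifted copies, and the observed share goes from 2.28% to 13.4%.

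In all, 2528 of 20033 protein-coding genes (12.6%) had a summit within 1 kb of an end, against a mean of 1495 with random placement. The 10 genes with the highest fold there were FAM135B (15.4), CSNK1G3, a casein kinase gene (14.6), IL27RA and RLN3, neighbours that share 1 peak (13.5), TRPM3, a cation channel gene (13.5), PSORS1C2 (12.4), P4HA3, a collagen prolyl hydroxylase gene (11.8), SH3GL2, which encodes an endophilin (11.8), ZNF768 (11.8) and CDC42SE1 (11.6). The CSNK1G3 summit at chromosome 5, 123511820, lay 357 bp outside the gene, and the TRPM3 summit at chromosome 9, 71447130, lay 159 bp outside. The shared IL27RA and RLN3 summit at chromosome 19, 14032194, lay 432 bp inside IL27RA and 643 bp outside RLN3. These peaks rested on 20 to 29 fragments each. A summit near the ends of neighbouring genes counts for each of them. The peaks of CDC42SE1 and of NDUFV3, named below, are also shared with a neighbouring gene.

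No list of the 16 fixed beforehand passed the test of gene-end summits against other protein-coding genes, in two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. The smallest unadjusted p was 0.137 and the smallest adjusted p 0.763, and 0 lists had an unadjusted p under 0.05. Among 39 ferroptosis suppressors, 3 had such a summit (7.69%, Fisher's exact test, adjusted p = 0.763): VKORC1L1, a vitamin K reductase gene, with a fold of 5.12 from 8 fragments, and ACSL3 and AKR1C1 with 3.45 from 5 fragments each. Among 44 ferroptosis drivers, 2 had one (4.55%, exact test, adjusted p = 0.763): GLS2, the mitochondrial glutaminase, with a fold of 6.28 from 21 fragments, and ATG5, an autophagy gene, with 2.36. Among 46 antioxidant enzymes, 9 had one (19.6%, exact test, adjusted p = 0.763), led by GSTP1, a glutathione transferase gene (6.97), PRDX6, a peroxiredoxin gene (6.24), MSRB3, a methionine sulfoxide reductase gene (5.52), and CAT, the catalase gene (5.08). Iron metabolism had 5 of 42 (11.9%, exact test, adjusted p = 1), led by PCBP1 (6.07), an iron chaperone gene, and CP (4.16), the ceruloplasmin gene.

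Interferon and antigen presentation genes had 4 of 53 (7.55%), led by CIITA (fold 7.36), the activator of MHC class II genes, and HLA-E (6.20). Immune checkpoints had 5 of 34 (14.7%), led by TNFRSF14 (7.66) and TIGIT (4.34). Squamous keratinocyte identity, the lineage of HSC3, had 4 of 47 (8.51%), led by GRHL3 (6.45) and TRIM29 (6.25), and epithelial-mesenchymal transition 4 of 45 (8.89%), led by TGFBR2 (5.68) and SMAD3 (4.57). AP-1 and stress transcription factors had 3 of 38 (7.89%), led by NFE2L1 (5.40) and CEBPB (5.31). Cell cycle genes had 7 of 49 (14.3%), led by RRM1 (5.69) and CDK1 (5.18), and cohesin and DNA damage response genes 3 of 44 (6.82%), led by ATR (4.56) and TOPBP1 (4.01). Oxidative phosphorylation had 10 of 76 (13.2%), led by NDUFV3 (9.59) and COX8A (8.56), and cytosolic ribosomal proteins 13 of 78 (16.7%), led by RPL35A (10.1) and RPS6 (6.06).

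Genes of lineages that a squamous carcinoma line should not use had a gene-end summit in 18 of 120 (15.0%), against 12.6% of all protein-coding genes. Without strand, whether these summits lie at starts or far ends is not known. Haematopoietic genes had 8 of 38 (21.1%), the highest share of the 16 lists, led by CD4 (fold 5.74) and CD8A (5.52). Their odds ratio of 1.85 fell to 0.987 with a fold of at least 5 and to 0, with 0 genes left, with a −log10 q of at least 5. Neuronal genes had 6 of 39 (15.4%), among them SYT1 (6.24), and hepatocyte and muscle genes 4 of 43 (9.30%), led by AHSG (6.03) and APOC3 (5.68). The neuronal odds ratio did not fall in the same way: it was 1.26, then 1.48 with the stricter fold (3 genes left) and 1.56 with the stricter q (2 left). That of hepatocyte and muscle genes was 0.710, then 0.866 and 0.688. None of these was called. With the wider 3 kb window, ferroptosis drivers had a summit less often (4 of 44, odds ratio 0.277) and haematopoietic genes more often (18 of 38, odds ratio 2.50), both with an adjusted p = 0.0479 in Fisher's exact test. In simulated lists of 40 genes, the background was raised by hand to about the observed share. A planted share of 25% was called in 26 of 100 simulations and a planted share of 50% in 100 of 100. A share of 25% was therefore mostly not detectable in a list of this size. Only shares above the background were planted. Whether a shortfall, such as that of ferroptosis suppressors and drivers at 1 kb, could be called was not tested.

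**Figure D3:**
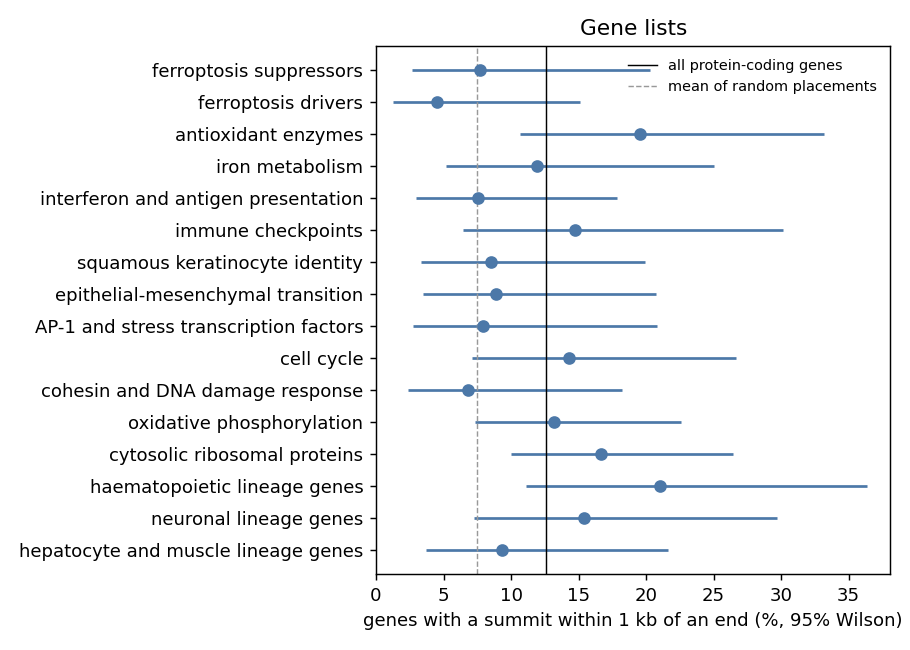
Share of each gene list with a summit within 1 kb of a gene end (horizontal axis, percent), with points for the 16 lists and bars for Wilson 95% intervals. The solid line is all protein-coding genes (12.6%) and the dashed line the mean of random placements (7.46%).

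Peak density differed between chromosome stretches. The left stretch of chromosome 5 (20349 to 46098516) had 25.7 peaks per Mb (exact Poisson 95% interval 24.2 to 27.2), and the right stretch of chromosome 18 (20946906 to 80247514) had 11.8 (10.98 to 12.7). On chromosome 3, the left stretch had 15.5 per Mb and the right stretch 24.0. Gene-rich chromosome 19 had 13.5 and 14.4 per Mb in its left and right stretches. Chromosome 17, also gene-rich, had 20.9 and 22.2.

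**Figure D4:**
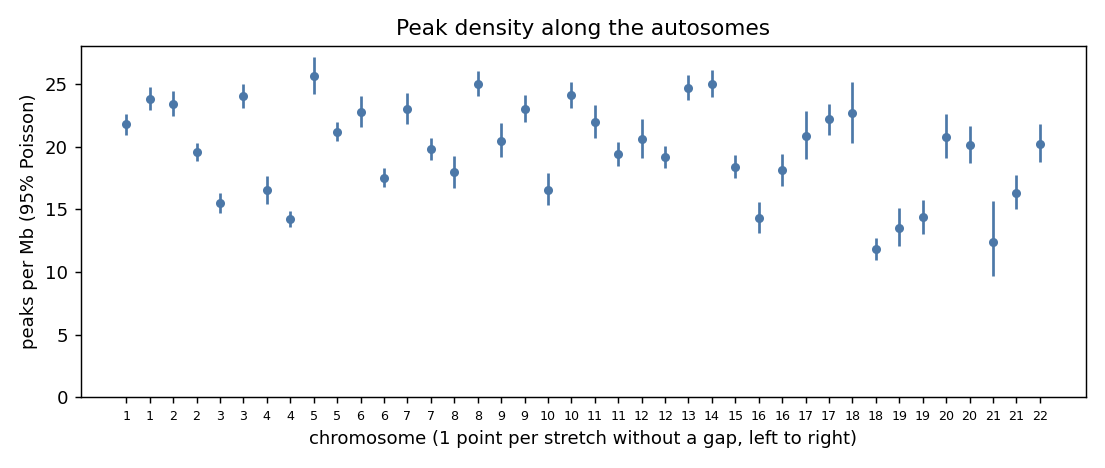
Peaks per Mb (vertical axis) in each autosomal stretch without a gap of over 1 Mb between annotated genes or peaks (horizontal axis, by chromosome), with points for the stretches and bars for exact Poisson 95% intervals. Chromosome 5 left stands at 25.7 and chromosome 18 right at 11.8. The bars cover counting error only.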

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

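The tests of mitochondrial pseudogenes, of gene ends, of gene number and of background reads were chosen after the results were seen; the test of bins 10 Mb apart was set before its value was computed.

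The mitochondrial genome, which the report's comparisons leave out, had 1 peak that covered positions 33 to 16569 at a fold of 2.94 over the background, from 8354 fragments, a number recovered outside the tolerance of 0.001. A further 149 peaks lay on 48 unplaced or unlocalised sequences, of which the highest had a fold of 11.3 from 19 fragments. Every listed peak stands above its recovered background by construction, with a lowest fold of 1.34, so standing above it does not set these peaks apart. The library of that background is not named in the sources used here.

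Nuclear copies of mitochondrial DNA held several of the peaks with the highest −log10 q. MTRNR2L12 on chromosome 3 (96617188 to 96618067) had 772 fragments and a −log10 q of 205, and the neighbours MTND1P23 and MTND2P28 on chromosome 1 (629302 to 629997) had 644 and 117. The background was high at both places too, at 145 and 164 fragments against a floor of 0.523, with folds of 4.50 and 3.32. Reads shared between mitochondrial DNA and its copies are a candidate explanation. Of 487 annotated mitochondrial pseudogenes, 27 overlapped a peak (5.54%), against 1444 of 16564 other pseudogenes (8.72%), and with 10 length classes the odds ratio was 0.906 (95% interval 0.608 to 1.35). That interval spans 1. The test counts overlap with any peak and does not use fragment numbers, so it cannot decide whether shared reads made the deep peaks. The question stays open, and no biological explanation was tested.

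The gathering of summits at gene ends is the second pattern. Gene-rich stretches as the cause are argued against by the copies shifted by 5 to 50 kb, since the observed number was 1.64 times the highest of 8 copies (counting interval 1.57 to 1.70). Open chromatin at active genes, cut without the antibody, stays open. Ribosomal and oxidative phosphorylation genes had a gene-end summit in 23 of 154 and genes of other lineages in 18 of 120, an odds ratio of 0.995 whose interval of 0.484 to 2.07 is too wide to decide. Binding of tagged PD-L1 stays open too, untested, since it needs the control libraries at the same places.

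The third pattern is the difference in density between stretches, and more genes in the denser ones is argued against: across 2686 bins of 1 Mb the rank correlation of peaks with protein-coding genes was -0.00377 (bootstrap interval -0.0869 to 0.0776), against 0.426 between neighbouring bins. Large stretches present in more copies stay an untested hypothesis. Bins 10 Mb apart still correlated at 0.305 (0.208 to 0.391), but pairs were pooled over stretches without removing each stretch's mean density. Stretches that differ in density give such a correlation by themselves, so this test restates the pattern and cannot decide its cause. Across 40 stretches, denser ones also had a larger share of peaks with a background above the floor (rank correlation 0.633, 0.319 to 0.842). The recovered backgrounds sit on whole unscaled fragments in 7519 of 29202 peaks and on whole scaled anti-Flag fragments in 0, so this is in line with more reads in a separate background library as well. Copy number was not measured, any cause that acts over 10 Mb would give the same correlation, and no biological explanation was tested.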

How the results depend on the processing

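Of the alternatives, the shifted copies, the divergent-transcript ends at 1 kb and 500 bp, a −log10 q of at least 10 and the gene spans were chosen after seeing the data. The excess at gene ends stayed above 1 under every alternative run: 1.70 in the report, 1.39 at 3 kb, 2.06 with a −log10 q of at least 5, 1.78 with a fold of at least 5, 1.65 with any overlap 1.70 against shifted copies and 2.82 with a −log10 q of at least 10. The share of summits was 9.56% at 3 kb, 5.16% with any overlap, 5.31% with the stricter q, 7.71% with a −log10 q of at least 10 and 4.54% with the stricter fold. Genes with a gene-end summit numbered 5308 at 3 kb, 670 with the stricter q and 1068 with the stricter fold, fewer by construction in the last 2, and 47 of 526 where only ends beside a divergent transcript count. Genes with a summit at the start only outnumbered those with one at the far end only 1.73 times at 1 kb and 1.75 times at 500 bp, where the call ended with fewer genes (exact p = 0.0961). Peaks numbered 11679 with the stricter q and 22393 with the stricter fold. Of the 45 genes the naming rule picks by their gene-end summit, 25 kept one with the stricter q and 37 with the stricter fold. A stricter q cannot add summits at CD274, so its 0 says nothing about stability.

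The list test called 2 lists at 3 kb and 0 under every other setting, including gene spans against length-matched lists (2 lists with an unadjusted p under 0.05, smallest adjusted p 0.184). The 2 called lists at 3 kb had odds ratios of 0.277 (ferroptosis drivers) and 2.50 (haematopoietic), and the cause was not tested. Odds ratios that crossed 1, none of them called, were, at 3 kb, immune checkpoints 0.853, squamous identity 1.18, epithelial-mesenchymal transition 1.25, cell cycle 0.711, cohesin 1.16, oxidative phosphorylation 0.625 and hepatocyte and muscle 1.49; with any overlap, cell cycle 0.942, oxidative phosphorylation 0.957 and hepatocyte and muscle 1.0999; with the stricter q, interferon 1.13, immune checkpoints 0.876, squamous identity 1.29, and cell cycle and haematopoietic 0; with the stricter fold, immune checkpoints 0.538, ribosomal proteins 0.960 and haematopoietic 0.987. The direction of these lists is therefore not resolved, and the cause was not tested. One start site per gene, placement and lists matched on base composition, and all motif alternatives were not run. No paired analysis was possible because each group has 1 library and 1 peak list was analysed. Depth limits single peaks: a median summit has 8 fragments.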

Other observations

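The values in this part were chosen after the data were seen. A pair of long genes held more summits than their surroundings. AUTS2 (chromosome 7, 69598475 to 70793506), a neurodevelopmental gene, had 33 summits where the density within 2 Mb gives 11.7, and CTNNA2 (chromosome 2, 79185377 to 80648780), a neuronal catenin gene, had 51 where it gives 24.2. They were the 2 of 20033 protein-coding genes past an exact one-sided Poisson test with Benjamini-Hochberg adjustment (adjusted p = 0.00493 and 0.0137), and 986 had an unadjusted p under 0.05. In 3 simulations with random placement the same test called 0 genes, and with 200 genes planted at 3 times their density it called 136 to 148 of them and 143 to 162 genes in all, so some calls fell on genes that were not planted (143 of 162 calls were planted genes in the simulation with the most calls). Density varies more between bins than a Poisson count (variance over mean 2.53 per 1 Mb), so these p-values are too small.

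Relative to random lists of the same size and gene length, ferroptosis suppressors had a summit in or near their span in 13 genes (random median 20, percentile 0.575) and antioxidant enzymes in 27 (random median 21, percentile 98.2). From 10000 random lists, as a permutation test, neither passed adjustment over the 16 lists (adjusted p = 0.184 and 0.294).

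Among the 10 peaks with the highest −log10 q, a pair of nuclear ones had folds under 2 over a high background. A peak in SNHG14 on chromosome 15 (25292090 to 25292428) had 19340 fragments against a background of 10077, a fold of 1.63. A peak in TET3 on chromosome 2 (74113432 to 74114128) had 7668 against 4858, a fold of 1.34, and its fragment number was recovered outside the tolerance of 0.001. Others of the 10 had higher folds, such as the ADAMTS13 peak at 15.88 over a background of 0.669.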
